A study of Sciaenops ocellatus with 36 samples.

How the data were processed

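RNA libraries of red drum embryos and larvae (TruSeq preparation, HiSeq2500 sequencing per the labels) were deposited as 6 tables of 56346 rows. Each table names 1 comparison of oil with control and holds whole-number values for each library. The read counts in the deposited library columns are raw counts, as shown by whole numbers with a different total in each library. The deposited log2 fold changes are, per the file headers, DESeq2 results of the authors for oil over control. The deposited p-values and adjusted p-values are also those of the authors' DESeq2 fit, per the file headers. HTSeq, DESeq2 and the human genome build hg19 are named in the submitters' processing notes, without versions and without the part each played. Rows carry human gene symbols although the organism is red drum, and how fish reads were assigned to them, the aligner and the reference sequence are not given in the sources used here. A symbol therefore stands for whatever fish transcripts were assigned to it, fish paralogs may be merged, and no fish genome position can be given.

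Groups were taken from the sample labels, and each column was matched to a sample by the library name in its header. Of 37 library columns 1 could not be matched to a sample; it stood among the controls of the 24 hpf source-oil table and was not used. Several headers contradict the table they stand in. The columns deposited as source oil at 48 hpf are the 3 slick-series controls of that age, with identical counts. The third control column of the 24 hpf slick-oil table is 1 of those libraries, and it was left out. The control columns of the 72 hpf slick-oil table are identical to the 3 source-series controls. In all, 6 libraries stand in more than 1 table, and 2 of the 12 groups in the labels have no column, so source oil at 48 hpf and slick-series controls at 72 hpf were not used here. The 24 hpf source-oil table assigns counts to symbols in another way than the other 5. Across symbols, the mean log2 CPM of its controls correlated with that of the slick-series controls of the same age at 0.507 (Pearson), against 0.986 for the 2 series at 48 hpf. ACTA2, for example, had 15350 CPM in its controls and 0 in the slick-series controls, and ACTC1 had 0 and 22400. Whether this affects fold changes within that table was not tested, and levels of single genes were not tested between it and the others.

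Each comparison was fitted on its own with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default filter on low counts (filterByExpr) and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested and a call at an adjusted p under 0.05. Levels are CPM after TMM scaling, so that control values shared by 2 comparisons can differ slightly between them. The SE of a log2 fold change is its size divided by the square root of F. Differences between oils or ages were tested in a joint edgeR fit of the libraries of both comparisons, except where the 24 hpf source-oil table took part. There, the difference of the log2 fold changes was divided by the root of the summed squared SE and given a normal p, two-sided. A normal p takes no account of the few libraries behind each SE. The smallest of these p-values are therefore too small and serve only to rank genes. Agreement between comparisons is given as correlations across genes, which are not independent replicates, and as overlaps of calls against the product of the counts divided by the genes in both. The effect of the shared controls at 72 hpf was simulated 20 times from counts with no oil effect.

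Before the data were examined, 32 lists of genes by function, the alternatives and the rule for named genes were written down. A list with at least 5 measured members was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists and comparisons, and 1 row stood for each symbol. The lists with a value for an estimated correlation in the report passed the preset test, and with the estimated correlation only the AHR list kept its call, in source oil at 24 and 72 hpf and slick oil at 24 and 72 hpf. The camera test compares a list with the other genes. Named genes are the 5 largest rises and 5 largest falls among called genes at or above the median level, up to 4 members with the smallest adjusted p from each list that passed or had 3 members called, and a fixed set of AHR, sterol, heart, eye and replication genes. For differences they are the 5 smallest adjusted p in each direction. Some genes chosen by this rule are not reported here by name; they stayed in every fit and list.

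The 2 groups of an oil comparison had 3 libraries each, except for slick oil at 24 hpf. The labels number the replicates of each group from 1 to 3. The column headers carry these numbers at 24 hpf and run from 4 to 9 at 48 and 72 hpf, so only the columns at 24 hpf could be linked to the labels. In the 24 hpf source-oil table the deviations from the group mean correlated across genes at 0.247, 0.122 and 0.310 for the libraries of the same number, so the numbers were taken to pair the samples there. Control 2 correlated better with oil library 1 (0.196), and oil library 2 better with control 3 (0.142), so this pairing is uncertain. The main fit, fixed beforehand, has no block, and the fit with the number as a block is an alternative. No sequencing date or batch is given in the labels. The number that ends each library name runs from 7 to 30 over the 20 control and source-oil libraries and from 4 to 12 over the 9 slick-oil libraries, and 6 numbers are used in both. The slick-oil libraries may therefore have been sequenced apart from all controls. Such a run would hold slick-oil libraries only, so it is confounded with slick oil in each of its comparisons, and no fit with it as a term could be made.

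The median count per gene tested lay between 77.8 and 116. Over 28 pairs of replicate libraries, Pearson's correlation across genes was 0.98 to 0.991, and the chi-square per degree of freedom against pure counting error was 1.45 to 6.68, so replicates differed by more than counting error. The tests were tried on simulated data with 200 changed genes and the spread of each table. A 2-fold change was found in 79.1% to 91.0% of genes and a 1.5-fold change in 41.8% to 71.6%, and 1.86% to 9.03% of the calls were false. The tests of differences, tried with 3-fold differences, found 83.5% to 99.0% with 4.57% to 6.97% false calls.

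The alternatives were: no filter; genes at or above the median level only; DESeq2 1.42.0; its size factors in edgeR; 1 row per symbol; the replicate block; thresholds of 0.01 and 0.1; a minimum absolute log2 fold change of 1; each library left out in turn; scaling the source-oil fold changes to slick oil; overlaps of the 500 smallest p-values; and other settings of the list test. Others were added after the data were seen: the 48 hpf library as an added slick-oil control, genes called between the 48 hpf controls left out, symbols within a factor of 2 between tables, 1 fit of the 5 tables with the same assignment, the replicate block in lists and differences of source oil at 24 hpf, and a block on the header number at 48 and 72 hpf. The size factors and the missing filter for joint differences, size factors for lists, and single libraries left out of differences, correlations and lists were also added then. Other splits of the libraries into groups of the same sizes were fitted for each comparison of at least 3 libraries per group.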

Results

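Polyadenylated RNA was sequenced from whole red drum (Sciaenops ocellatus), a coastal marine fish, at 24, 48 and 72 hours post-fertilization (hpf). The animals had been kept in water prepared with Deepwater Horizon crude oil, either source oil (labelled Mass oil) at 0.27% or weathered slick oil at 2.50%, or in clean water. The labels describe 36 samples in 12 groups of 3, each sample a pool of 30 embryos or larvae. The values compared here come from 29 libraries in 10 groups, 3 per group, except for 2 slick-series controls at 24 hpf. The total count per library was 4771973 to 5880716 in the 24 hpf source-oil table and 2532771 to 3280939 in the others. Genes are named by the human symbols of the deposited rows, and levels are in CPM (counts scaled to library size), as mean ± SD. The labels do not say whether the replicate pools came from separate spawns or tanks, so the p-values measure the spread between these samples.

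Source oil at 24 hpf was compared with clean water to ask which transcripts had already changed in embryos. Of 9793 genes tested, 531 were called, 390 higher and 141 lower with oil. With the replicate numbers as a block the count was 852, and without oil replicate 2 it was 344. The authors' deposited table has 350 genes past an adjusted p of 0.05, of which 347 were called here, all 347 in the same direction; it holds 4 control columns, 1 of which matched no sample and was not used here. CYP1A1, the cytochrome P450 that the aryl hydrocarbon receptor (AHR) switches on to oxidise aromatic hydrocarbons, rose from 134 ± 36.8 CPM (n = 3) to 2160 ± 184 CPM (n = 3), a log2 fold change of 4.01 (SE 0.13, edgeR adjusted p = 1.33e-14). The related CYP1B1 rose by 3.40, the receptor's repressor AHRR by 2.24, the poly-ADP-ribosyltransferase TIPARP by 0.62 and the drug-metabolising CYP3A4 by 1.64 on the log2 scale. In these 5 genes, as in the other called genes given here, each of the 3 oil libraries lay beyond all 3 controls. Of 15 measured genes of the AHR and xenobiotic list, 7 rose and 0 fell, or 8 adjusted over the list alone. Its adjusted p = 0.0455 with an estimated correlation, the same value as in the other oil comparisons at 24 and 72 hpf. The remaining genes with the largest rises were C1orf50 (log2 2.20), the matrix protein CRTAC1 (2.10), the sulfide-oxidising SQRDL (1.94) and the lysine-catabolic GCDH (1.85).

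Genes of the oxidative-stress list were higher in the same embryos: 13 of 20 rose and 0 fell, or 17 adjusted over the list alone (adjusted p = 0.0807 with an estimated correlation). PRDX1, a peroxide-reducing enzyme, went from 354 ± 17.5 to 711 ± 11.7 CPM (n = 3 each, log2 1.01, edgeR adjusted p = 2.26e-09). The autophagy receptor SQSTM1 rose by 1.60, the glutathione-synthesis subunit GCLM by 0.99 and PRDX6 by 0.95. Of 22 cholesterol-synthesis genes, 10 rose and 0 fell, or 16 adjusted over the list alone (adjusted p = 0.109 with an estimated correlation). DHCR7, the last enzyme of the pathway, rose by 1.17, MSMO1 by 1.11 and the sterol sensor INSIG1 by 0.73 on the log2 scale. SQLE rose by 1.16 (adjusted p = 0.0333), a call that was lost without control replicate 2 (0.97) or 3 (0.97) and without oil replicate 2 (1.06) or 3 (1.12). Chaperones rose in 9 of 21 cases, or 11 adjusted over the list alone, by less: HSPD1 by 0.53, HSPA5 by 0.48 and HSPA8 by 0.35 (adjusted p = 0.364 with an estimated correlation).

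Structural proteins of the lens fell at 24 hpf with source oil. Of 16 crystallins and other lens genes, 12 fell and 0 rose, or 12 adjusted over the list alone (adjusted p = 0.195 with an estimated correlation). CRYBB1 went from 473 ± 81.3 to 200 ± 86 CPM (n = 3 each, log2 -1.24, edgeR adjusted p = 0.000103). CRYBA1 fell by 1.26, CRYBA4 by 1.16, CRYBA2 by 1.11 and CRYBB3 by 1.34, and DESeq2 did not call these 4. The retinal genes RPE65, which regenerates visual pigment, and NR2E3, a photoreceptor transcription factor, each fell by 0.83. In the phototransduction list 4 of 23 genes fell, or 4 adjusted over the list alone (adjusted p = 0.495 with an estimated correlation). Of 29 cartilage and skeletal-matrix genes, 6 fell and 0 rose, or 15 called adjusted over the list alone, 1 of them higher (adjusted p = 0.364 with an estimated correlation). Among them were the collagen IX chains COL9A3 (-0.47) and COL9A2 (-0.40) and the proteoglycan FMOD (-0.92). The embryonic globin HBE1 fell by 2.0, with controls of 107 ± 41.4 and oil libraries of 25.9 ± 24.9 CPM (n = 3 each). Its log2 fold change was -3.20 without oil replicate 1, and DESeq2 did not call it. The hatching-gland protease ASTL fell by 1.22.

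Liver secretory transcripts moved the other way: 11 of 25 rose and 0 fell, or 13 adjusted over the list alone (adjusted p = 0.413 with an estimated correlation). They included complement CFB (log2 1.14), complement C3 (0.85), the fibrinogen chain FGB (0.72) and FETUB (0.57). Of 32 genes of glycolysis and gluconeogenesis, 10 rose, or 15 adjusted over the list alone (adjusted p = 0.223 with an estimated correlation), among them LDHA (1.2) and PCK1 (0.71). The inflammatory and cytokine-signalling genes PTGS2 (1.31), SOCS3 (1.09) and STAT3 (0.81) rose, in an innate-immunity list of 15 with 4 rises and a median of 0.07, or 5 called adjusted over the list alone, 1 of them lower. That list had adjusted p = 0.223 with an estimated correlation and 0.414 with ranks, and it also lost its call with a correlation of 0.05 and among genes at or above the median level. Heart-associated genes were split, 2 up and 2 down of 22 in the sarcomere list: CSRP3 rose by 0.68 and FHL2 fell by 0.79. The cardiac troponin TNNT2 did not pass the test (log2 0.07, adjusted p = 0.88), nor did the replication clamp PCNA (-0.17, adjusted p = 0.324). The calcium-release and calcium-pump genes RYR3 (0.44), ATP2A1 (0.49) and ATP2A2 (0.45), which shape the contraction cycle, rose, while the calcium-handling list did not pass as a whole (3 of 23 called, or 3 adjusted over the list alone, median 0.02, adjusted p = 0.249).

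**Figure D1:**
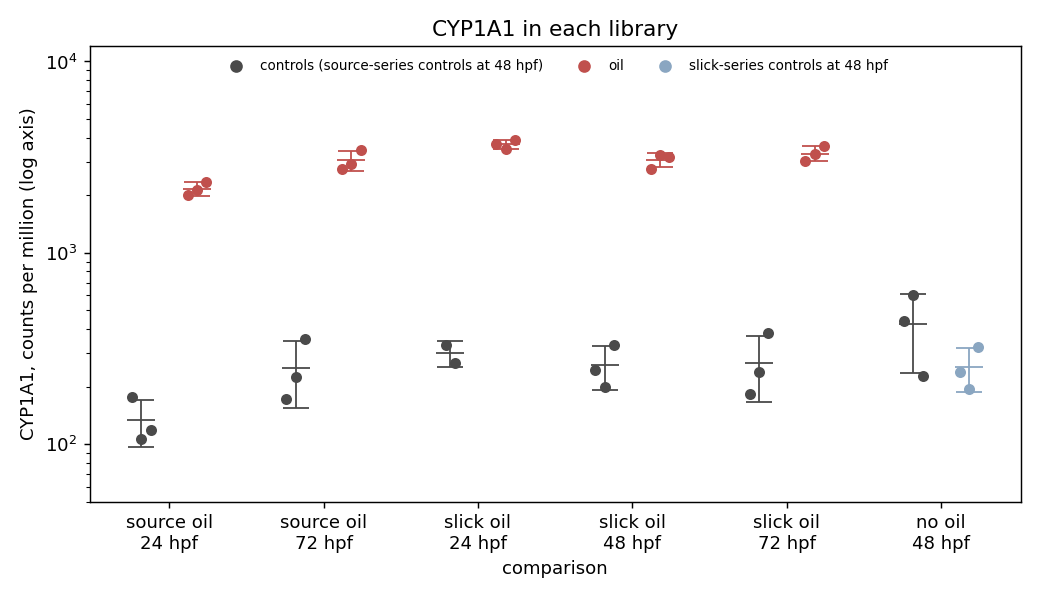
CYP1A1 in each library, in CPM on a log axis, for each comparison; dark points are controls, red points oil libraries, blue points the slick-series controls at 48 hpf, and bars show mean ± SD. Group means with oil lie between 2160 and 3690 CPM and those without oil between 134 and 423 CPM. The lowest of each, 2160 and 134 CPM, belong to the 24 hpf source-oil table, whose levels cannot be compared with the others.

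Source oil at 72 hpf was compared with clean water to follow the response into hatched larvae. Of 8983 genes tested, 1833 were called, 1021 higher and 812 lower with oil. The authors' deposited table has 1189 genes past an adjusted p of 0.05, and 1178 of them were called here in the same direction. CYP1A1 rose from 251 ± 95.3 to 3050 ± 365 CPM (n = 3 each, log2 3.60, SE 0.17, edgeR adjusted p = 7.15e-14). AHRR rose by 2.95, CYP1B1 by 3.41 and the forkhead factor FOXQ1 by 1.32. Of 16 genes of the AHR list, 9 rose and 0 fell, or 11 adjusted over the list alone. The inflammatory enzyme PTGS2, which makes prostaglandins, went from 75.3 ± 30 to 663 ± 259 CPM (n = 3 each, log2 3.14). The matrix protease MMP9 rose by 3.01 from controls of 7.61 ± 7.73 CPM, and by 4.26 without 1 control library. The growth factor FGF7 rose by 2.72. In the called genes given for source oil at 72 hpf, PER1 apart, the 3 oil libraries lay beyond all 3 controls.

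Photoreceptor genes fell together with source oil at 72 hpf. Of 31 phototransduction genes, 25 fell and 0 rose, or 25 adjusted over the list alone (adjusted p = 0.0807 with an estimated correlation), with a median log2 fold change of -0.89. RPE65 went from 147 ± 9.61 to 54.6 ± 12.9 CPM (n = 3 each, log2 -1.44, edgeR adjusted p = 3.1e-09). The cone arrestin ARR3 fell by 1.26 and the cone kinase GRK7 by 1.2. The long-wave cone opsin OPN1LW had a log2 fold change of -7.97 that rested on 1 control library: controls were 215 ± 355 CPM (n = 3), and without that library the log2 fold change was -3.60. Of 11 lens genes, 10 fell, or 11 adjusted over the list alone (adjusted p = 0.223 with an estimated correlation); CRYBA1 went from 1180 ± 153 to 605 ± 69.2 CPM (log2 -0.96) and CRYBB2 fell by 0.91. Synaptic genes fell in 15 of 30 cases with 0 rises, or 19 adjusted over the list alone (adjusted p = 0.517 with an estimated correlation). They included the glutamate transporter SLC17A7 (-0.58) and the glutamate receptors GRIA3 (-0.40) and GRIA1 (-0.37).

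Of 21 sterol-synthesis genes 20 were higher and 0 lower, or 21 called adjusted over the list alone, 1 of them lower (adjusted p = 0.0807 with an estimated correlation). MSMO1 went from 87.5 ± 25.1 to 356 ± 57 CPM (n = 3 each, log2 2.03, edgeR adjusted p = 2.78e-11). LSS rose by 2.20 and SQLE by 3.87, the last from 0.666 ± 0.353 CPM. Of 21 oxidative-stress genes, 15 rose, or 18 adjusted over the list alone (adjusted p = 0.177 with an estimated correlation), led by PRDX1 (1.40), SQSTM1 (1.75) and PRDX6 (1.17). Proteasome subunits, which degrade damaged proteins, rose in 23 of 30 cases, or 28 adjusted over the list alone (adjusted p = 0.404 with an estimated correlation), for example PSMD1 (0.75) and PSMB5 (0.68). Chaperones rose in 11 of 18 cases, or 11 adjusted over the list alone (adjusted p = 0.364 with an estimated correlation), among them BAG3 (1.72) and DNAJB1 (1.06). Innate-immune genes rose in 11 cases and fell in 1 of 16, or 13 called adjusted over the list alone (adjusted p = 0.109 with an estimated correlation), among them REL (2.06) and STAT3 (0.91).

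Growth-related groups fell at the same age. Of 25 ribosome-biogenesis genes 20 fell, or 23 adjusted over the list alone (adjusted p = 0.223 with an estimated correlation), for example BOP1 (-0.67) and the RNA polymerase I subunit POLR1A (-0.72). Of 58 ribosomal proteins 49 fell, or 57 adjusted over the list alone, with a median of -0.36 (adjusted p = 0.495 with an estimated correlation). In the cell-cycle list 17 of 29 genes fell and 1 rose, or 23 called adjusted over the list alone (adjusted p = 0.231 with an estimated correlation), with falls in UBE2C (-1.25), AURKB (-0.78) and MCM6 (-0.77) and a rise in RRM2 (0.69). PCNA did not pass the test (-0.28, adjusted p = 0.251). The sarcomere list was not called as a whole (adjusted p = 0.409), although MYL7, the atrial myosin light chain, fell by 1.83 and FHL2 by 0.83. TNNT2 fell by 0.68 (adjusted p = 0.0096), a call lost without 1 oil library (-0.59) and with DESeq2. In the calcium-handling list 6 of 21 genes rose, JPH2 (0.56) and CASQ1 (0.54) among them, and 2 fell, or 12 called adjusted over the list alone, and the list did not pass (median 0.01, adjusted p = 0.382). Glucose metabolism was split, with falls in the glucose-releasing G6PC (-1.21) and rises in the hexokinases HK1 (1.00) and HK2 (1.04).

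Slick oil at 24 hpf was compared with clean water to see what weathered oil changed in embryos. This comparison had 3 oil and 2 control libraries, because the third control column of that table is named as a 48 hpf library. By the numbers in their names, the slick-oil libraries of all 3 ages may have been sequenced apart from every control, so slick oil and run cannot be separated in its comparisons. Of 8962 genes tested, 196 were called, 145 higher and 51 lower. With the 48 hpf library as an added control the count was 17. It was 63 without control replicate 2, 96 without control replicate 3, 100 without oil replicate 1 and 489 without oil replicate 3. The authors' deposited table has 51 genes past an adjusted p of 0.05, all 51 of them called here in the same direction. CYP1A1 rose from 298 ± 46 CPM (n = 2) to 3690 ± 214 CPM (n = 3), a log2 fold change of 3.63 (SE 0.10, edgeR adjusted p = 1.13e-19). CYP1B1 rose by 3.38, AHRR by 2.24, CYP3A4 by 2.04, SQRDL by 2.17 and CRTAC1 by 1.92, each in 3 of 3 oil libraries. In the AHR list 5 of 17 genes rose and 0 fell, or 7 adjusted over the list alone.

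Oxidative-stress genes rose in 10 of 21 cases with slick oil at 24 hpf, or 15 adjusted over the list alone (adjusted p = 0.057 with an estimated correlation). PRDX1 went from 425 ± 7.95 (n = 2) to 824 ± 55.7 CPM (n = 3, log2 0.96, edgeR adjusted p = 5.57e-09) and SQSTM1 rose by 1.47. In the respiratory-chain list 5 of 37 genes rose, or 7 adjusted over the list alone (adjusted p = 0.176 with an estimated correlation), among them the complex II subunits SDHB (1.23) and SDHA (1.08). LDHA rose by 2.47 from 6.67 ± 0.304 CPM (n = 2), and FECH, the last enzyme of heme synthesis, by 1.22. Of 26 cartilage and skeletal-matrix genes, 9 fell, or 9 adjusted over the list alone (adjusted p = 0.0807 with an estimated correlation). The collagen gene COL5A2 fell by 0.38 and the proteoglycan DCN by 0.63. Both calls were lost without control replicate 2 (-0.34 and -0.66), and that of DCN also without control replicate 3 (-0.60). The flavin monooxygenase FMO5 fell by 0.89, CRISP3 by 0.83 and the matrix protease ADAMTS12 by 0.74. With the 48 hpf library as an added control, CYP1A1, AHRR, CYP1B1, CYP3A4, SQRDL, CRTAC1, PRDX1, SQSTM1 and SDHB stayed past the test, and the other called genes given here did not. Of 18 cholesterol-synthesis genes 2 rose, or 2 adjusted over the list alone (adjusted p = 0.223 with an estimated correlation). The lens list did not pass its test (11 genes, median log2 0.07, adjusted p = 0.152).

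Slick oil at 48 hpf was compared with its own clean-water controls to bridge the embryonic and larval ages. Of 9091 genes tested, 244 were called, 175 higher and 69 lower. The count fell to 121 without the second control library, 121 without the third, 102 without the second oil library and 141 without the third, and it was 941 without the first oil library. The authors' deposited table has 208 genes past an adjusted p of 0.05, and 179 were called here in the same direction. CYP1A1 rose from 259 ± 66.7 to 3070 ± 272 CPM (n = 3 each, log2 3.57, SE 0.14, edgeR adjusted p = 7.6e-10). AHRR rose by 1.60, CYP1B1 by 2.89, CYP3A4 by 1.76, FGF7 by 2.33 and SQRDL by 1.81, each in 3 of 3 oil libraries. In the AHR list 5 of 17 genes rose, or 7 adjusted over the list alone (adjusted p = 0.057 with an estimated correlation).

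Genes of protein turnover and antioxidant defence were among the rises with slick oil at 48 hpf. All 30 proteasome subunits were called adjusted over the list alone, each of them higher, and 17 over all genes tested (median log2 0.43, adjusted p = 0.281 with an estimated correlation). PSMB5 went from 263 ± 15 to 388 ± 39.9 CPM (n = 3 each, log2 0.56, edgeR adjusted p = 0.00179). Oxidative-stress genes rose in 12 of 21 cases, or 19 called adjusted over the list alone (adjusted p = 0.0807 with an estimated correlation), with SQSTM1 at 2.16, PRDX1 at 1.04, PRDX6 at 1.02 and the glutathione-synthesis enzyme GCLC at 0.95. Cholesterol-synthesis genes rose in 6 of 20 cases, or 11 adjusted over the list alone (adjusted p = 0.109 with an estimated correlation): MSMO1 by 1.33, CYP51A1 by 1.08 and DHCR7 by 0.70. Photoreceptor genes fell in 9 of 31 cases with 0 rises, or 20 adjusted over the list alone (median log2 -0.64, adjusted p = 0.322 with an estimated correlation). The guanylate-cyclase activator GUCA1A fell by 1.62 and RPE65 by 0.64. Of 15 pigment-cell genes 2 fell, or 3 adjusted over the list alone (adjusted p = 0.364 with an estimated correlation), among them TYR, the rate-limiting enzyme of melanin synthesis, by 0.60. Of 29 cartilage and skeletal-matrix genes 1 fell over all genes tested, or 20 called adjusted over the list alone (adjusted p = 0.223 with an estimated correlation). The water channel AQP8 fell by 1.74 and HBE1 by 0.80.

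Slick oil at 72 hpf was compared with clean water to see what weathered oil changed in hatched larvae. The control columns of this table are the source-series controls, so both oils share 3 control libraries at this age. Oil and series, and possibly sequencing run, therefore differ together between its groups. The difference between the series without oil at 48 hpf is given with the lists that passed in the next 3 paragraphs. Of 8972 genes tested, 1673 were called, 767 higher and 906 lower. The authors' deposited table has 968 genes past an adjusted p of 0.05, and 962 were called here in the same direction. CYP1A1 rose from 267 ± 102 to 3300 ± 293 CPM (n = 3 each, log2 3.63, SE 0.16, edgeR adjusted p = 4.6e-17). CYP1B1 rose by 3.61, AHRR by 2.93, FGF7 by 2.84, FOXQ1 by 1.5, the fibrocystin-like PKHD1L1 by 2.12 and the kinase ADCK4 by 1.68. Without oil at 48 hpf PKHD1L1 was already higher by 1.07 in the slick series. Of 16 AHR-list genes 8 rose, or 8 adjusted over the list alone. In the called genes given for slick oil at 72 hpf the 3 oil libraries lay beyond all 3 controls.

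Ribosomal proteins were lower with slick oil at 72 hpf than in the source-series controls in 58 of 58 cases, or 58 adjusted over the list alone, with a median log2 fold change of -0.80 (adjusted p = 0.181 with an estimated correlation). RPLP0 went from 385 ± 26.3 to 212 ± 3.74 CPM (n = 3 each, log2 -0.86, edgeR adjusted p = 4.15e-09), and RPS16 fell by 1.04. Without oil at 48 hpf they were already lower in the slick series, 30 of 58, or 52 adjusted over the list alone, with a median of -0.32 and RPS16 at -0.55 (adjusted p = 0.32 with an estimated correlation), so part of this fall may belong to the series. Cell-cycle genes fell in 20 of 27 cases, or 21 adjusted over the list alone (adjusted p = 0.196 with an estimated correlation), including CDK1 (-1.15), AURKB (-1.26), TYMS (-1.33) and PCNA (-0.95), where 1 of 35 was lower between the series without oil, or 4 adjusted over the list alone (median -0.33, adjusted p = 0.387 with an estimated correlation). Of 24 skeletal-muscle genes 11 fell, or 11 adjusted over the list alone (adjusted p = 0.52 with an estimated correlation), among them the energy-supply genes PGAM2 (-0.78), PFKM (-0.62) and PYGM (-0.59). Between the series without oil 1 of 25 muscle genes was lower, or 2 adjusted over the list alone (median -0.11, adjusted p = 0.605 with an estimated correlation). The heart genes MYL7 and TNNT2 fell by 1.21 and 0.92, while the sarcomere list did not pass as a whole (adjusted p = 0.424). The limb and heart factor TBX5 rose by 0.92.

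Digestive and hepatic transcripts were lower with slick oil at 72 hpf than in the source-series controls, and some were also lower in the slick series without oil at 48 hpf. Of 26 liver genes 14 fell and 1 rose, or 16 called adjusted over the list alone (adjusted p = 0.354 with an estimated correlation). The lipoprotein genes APOA4 and APOB fell by 1.84 and 1.13, and the prothrombin gene F2 by 1.01. Pancreatic and gut enzymes fell in 10 of 17 cases and rose in 2, or 14 called adjusted over the list alone (adjusted p = 0.525 with an estimated correlation). PRSS1, trypsin, went from 26900 ± 5510 to 14900 ± 1830 CPM (n = 3 each, log2 -0.85, edgeR adjusted p = 1.3e-05), and the elastase CELA1 fell by 1.03. Of 14 yolk and lipid-transport genes 9 fell and 1 rose, or 12 called adjusted over the list alone (adjusted p = 0.109 with an estimated correlation), such as DGAT2 (-0.92) and LCAT (-0.83). In glucose metabolism 13 of 31 genes fell and 3 rose, or 20 called adjusted over the list alone (adjusted p = 0.414 with an estimated correlation), with falls in G6PC (-1.07) and FBP1 (-0.85). Between the series without oil, 5 of 22 liver genes were lower, or 6 adjusted over the list alone (APOA4 -1.2), 10 of 15 gut genes, or 12 (CELA1 -1.5), and 4 of 11 yolk genes, or 8 (DGAT2 -0.96, LCAT -0.66). Of 31 genes of glucose metabolism 4 were lower there, or 5 called adjusted over the list alone, 1 of them higher. These 4 lists had adjusted p = 0.223, 0.223, 0.0807 and 0.525 with an estimated correlation, in that order. These falls can therefore not be assigned to oil alone. The largest fall was that of OVGP1, a chitinase-family glycoprotein, by 2.26, and the mitochondrial uncoupler UCP1 fell by 1.66.

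Eye genes fell with slick oil at 72 hpf as well, 16 of 30 in phototransduction, or 19 adjusted over the list alone (adjusted p = 0.223 with an estimated correlation), and 10 of 11 in the lens, or 11 adjusted over the list alone (adjusted p = 0.364 with an estimated correlation). GNB3 went from 907 ± 146 to 429 ± 36.2 CPM (n = 3 each, log2 -1.08, edgeR adjusted p = 1.47e-09), and RPE65 fell by 1.05 and CRYGN by 0.69. Between the series without oil 5 of 31 phototransduction genes were lower, or 11 adjusted over the list alone (median -0.25, adjusted p = 0.385 with an estimated correlation), and 0 of 11 lens genes, or 0 (median 0.01). Cholesterol-synthesis genes rose in 16 of 21 cases and fell in 1, or 18 called adjusted over the list alone (adjusted p = 0.356 with an estimated correlation): SQLE by 3.34 and MSMO1 by 1.17. Oxidative-stress genes rose in 13 of 21 cases and fell in 2, or 15 called adjusted over the list alone (adjusted p = 0.364 with an estimated correlation), with PRDX1 up by 1.14 and the peroxisomal catalase CAT down (-0.96). Between the series without oil 1 of 19 cholesterol-synthesis genes was higher, or 1 adjusted over the list alone, and 3 of 19 oxidative-stress genes were lower, or 5 adjusted over the list alone (adjusted p = 0.414 with an estimated correlation).

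**Figure D2:**
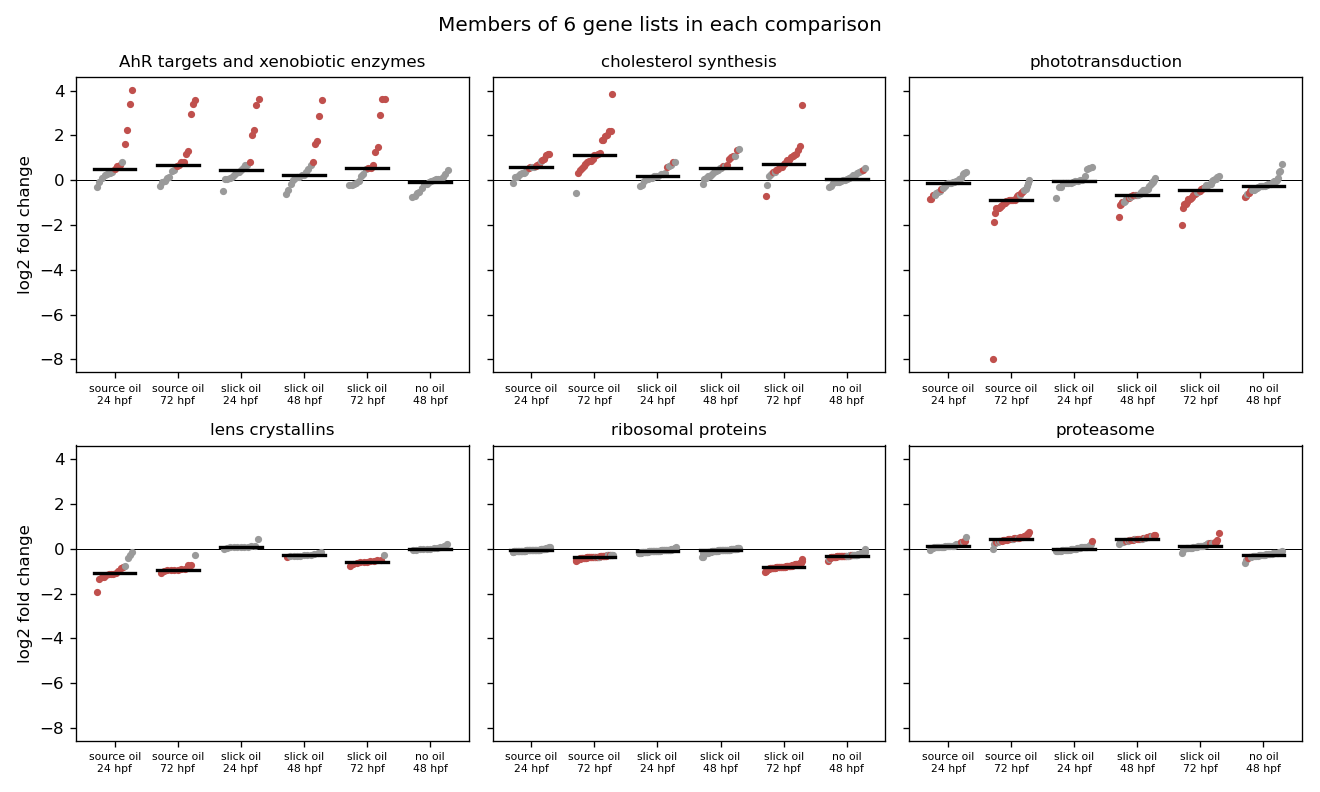
Log2 fold changes of the members of 6 gene lists in each comparison (the last is slick-series over source-series controls); each point is a gene, sorted by value, red where the adjusted p was under 0.05 and grey otherwise, and black bars mark the medians. Photoreceptor medians were -0.89, -0.64 and -0.42 with source oil at 72 hpf and slick oil at 48 and 72 hpf, and the ribosomal-protein median with slick oil at 72 hpf was -0.80; the lowest photoreceptor point is OPN1LW, which rested on 1 control library.

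At 48 hpf the controls of the slick series were compared with the controls of the source series, to see how the series differed with no oil. The columns deposited as source oil at this age are named as slick-series controls, so source oil at 48 hpf was not analysed here. Of 9100 genes tested, 405 were called, 186 higher and 219 lower in the slick series. That was more than with slick oil against controls of its own series at 24 hpf (196) or 48 hpf (244). Those comparisons stay within 1 series, so this count is not a background for them. The count was 1202 without the first source-series control, 114 without the second and 96 without the third, and 110 without the second slick-series control and 115 without the third. The authors' deposited table has 303 genes past an adjusted p of 0.05, and 263 were called here in the same direction. CYP1A1 did not pass the test (423 ± 187 against 252 ± 64.8 CPM, n = 3 each, log2 -0.75, edgeR adjusted p = 0.0513). Pancreatic and gut enzymes were lower in 10 of 15 cases, or 12 adjusted over the list alone (adjusted p = 0.223 with an estimated correlation), among them the brush-border lactase LCT (-1.61) and CELA1 (-1.5). Ribosomal proteins were lower in 30 of 58 cases, or 52 adjusted over the list alone (adjusted p = 0.32 with an estimated correlation), for example RPS16 (-0.55). The growth-factor-binding gene IGFBP1 was higher (1.27), as were PKHD1L1 (1.07) and the nuclear exporter XPO1 (0.82). Respiratory-chain genes were lower in 7 of 37 cases, or 15 adjusted over the list alone (adjusted p = 0.0807 with an estimated correlation). The proteasome list also passed the preset test (camera, adjusted p = 0.444 with an estimated correlation). Its 4 genes with the smallest adjusted p were lower: PSMA6 (-0.41), PSMA2 (-0.38), PSMC2 (-0.35) and PSMD14 (-0.32), the last not called.

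Whether the oils differed at 24 hpf was tested gene by gene on the difference of the log2 fold changes (z test with normal p and Benjamini-Hochberg adjustment). The doses differed, and the source-oil table assigns counts to symbols in another way than the slick-oil table, so the same symbol may stand for different transcripts. Of 8396 genes, 63 differed, 33 with a higher and 30 with a lower value in slick oil. The count was 38 with the source-oil fold changes scaled to slick oil and 112 with the replicate numbers as a block in the source-oil fit. It was 116 without source-oil control replicate 3, 157 without source-oil replicate 1, 37 without source-oil replicate 2, 37 and 34 without slick control replicates 2 and 3, and 179 without slick-oil replicate 3. Lens genes gave the clearest group: 10 of 11 were higher in slick than in source oil, or 10 adjusted over the list alone. CRYBB1 had log2 fold changes of -1.24 with source and 0.12 with slick oil, a difference of 1.36 (SE 0.20, z test, adjusted p = 2.62e-08). This normal p ignores the few libraries behind the SE and is too small. The macrophage mannose receptor MRC1 differed by 1.95 and the protease CAPN3 by 1.02. Liver genes were lower in slick oil in 6 of 19 cases, or 12 adjusted over the list alone, including C3 (-1.04), and the endothelial lipase LIPG differed by -1.89.

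The same fold changes were related across the genes both oils had in common at 24 hpf, where genes are not independent replicates. Pearson's correlation was 0.43 and Spearman's 0.244 over 8396 genes. Of 141 genes called with both oils, 140 had the same sign: 120 rose in both against 5.52 given by the product of the counts, and 20 fell in both against 0.741 (Fisher's exact test, p = 1.19e-156 and 1.64e-24).

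At 72 hpf both oils were compared in 1 joint fit, in which the shared controls drop out of the difference. Series, and possibly sequencing run, differ together with the oil. Of 9185 genes, 1470 differed, 673 with a higher and 797 with a lower value in slick oil (edgeR quasi-likelihood test). The count was 974 without the second source-oil library and 966 without the second slick-oil library. Clock genes went both ways, 7 of 18 higher and 6 lower with slick oil, or 10 and 7 adjusted over the list alone, and the list did not pass (adjusted p = 0.285). PER3 had log2 fold changes of -0.38 with source and 1.32 with slick oil, a difference of 1.72 (SE 0.17, adjusted p = 3.25e-08), and PER1 differed by 1.71; between the series without oil PER3 was higher by 0.45. The call of PER1 with source oil (-0.72) was lost without 1 control library (-0.26). ARR3 had log2 fold changes of -1.26 with source and -0.22 with slick oil (difference 1.06) and the channel CNGA3 of -1.26 and -0.16 (1.12), and 14 of 30 phototransduction genes were higher, or 15 adjusted over the list alone. Synaptic genes were higher with slick oil in 20 of 30 cases, or 23 adjusted over the list alone, and without oil at 48 hpf in 2 of 30, or 7. The repressors BCL6B and BCL6 differed by -1.87 and -1.45, the activity-dependent factor NPAS4 by -2.45 and CAT by -1.16. Ribosomal proteins were lower with slick oil in 55 of 58 cases, or 56 adjusted over the list alone (median difference -0.40). Without oil at 48 hpf they were lower in the slick series as well, 30 of 58, or 52 adjusted over the list alone (median -0.32). Innate-immune genes were lower in 9 of 16 cases and higher in 1, and cholesterol-synthesis genes lower in 10 of 21.

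Across 8855 genes the log2 fold changes of both oils at 72 hpf had a Pearson correlation of 0.631 and a Spearman correlation of 0.561. Shared controls alone gave a mean Pearson correlation of 0.489 in 20 simulations, at most 0.511, and a mean Spearman correlation of 0.459. The covariance was 0.107 against 0.0187 simulated, a difference of 0.0883. Of 835 genes called with both oils, 809 had the same sign, 393 rising in both against 85.9 given by the product of the counts and 416 falling in both against 83. The simulations gave a mean of 0.15 genes called in both, at most 2. Part of the excess may come from the shared controls, which were too few to be divided into 2 sets of at least 2 libraries.

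Age was compared within each oil by the difference of the log2 fold changes. For slick oil between 24 and 48 hpf, 0 of 9498 genes differed in the joint edgeR fit, where 1078 had an unadjusted p under 0.05. The count was 190 without the first oil library at 48 hpf, 8 without oil replicate 3 at 24 hpf and 2 without the first control at 48 hpf. Proteasome genes had a higher value at 48 hpf in 27 of 31 cases adjusted over the list alone. The slick-series controls at 48 hpf were low in proteasome genes against the source series, which may add to this and was not tested. Of 97 genes called at both ages, 97 had the same sign, and 88 rose at both against 2.89 given by the product of the counts. The correlation across 8722 genes was 0.277 (Pearson) and 0.0763 (Spearman).

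Between 48 and 72 hpf, 674 of 9400 genes differed with slick oil, 278 higher and 396 lower at 72 hpf. The controls are of the slick series at 48 hpf and of the source series at 72 hpf, so this difference contains that between the series. The count was 351 without the third control at 48 hpf, 1191 and 363 without the first and second oil libraries at 48 hpf, 428 without the third control at 72 hpf and 429 without the second oil library at 72 hpf. Ribosomal proteins were lower at 72 hpf in 56 of 58 cases, or 57 adjusted over the list alone, and cell-cycle genes in 15 of 34, or 21 adjusted over the list alone. The clock gene NR1D2 changed from -0.60 to 1.22, a difference of 1.80 (SE 0.15, edgeR adjusted p = 8.5e-08), and the nucleotide-synthesis gene RRM2 differed by -1.13. Without oil at 48 hpf the slick series had RRM2 at -0.47 and NR1D2 at 0.09, and 30 of 58 ribosomal proteins lower, or 52 adjusted over the list alone. Of 169 genes called at both ages 158 had the same sign, with Pearson's correlation at 0.291 and Spearman's at 0.134 across 8765 genes.

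Between 24 and 72 hpf, 379 of 9551 genes differed with slick oil, 81 higher and 298 lower at 72 hpf, and 205 without control replicate 2 at 24 hpf. Here too the controls change from the slick to the source series, so age and series cannot be separated, least of all for ribosomal proteins, of which 30 of 58 were lower in the slick series without oil. Ribosomal proteins were lower in 57 of 58 cases, or 58 adjusted over the list alone, and lens genes in 9 of 11, or 11 adjusted over the list alone. NOTUM, which dampens Wnt signals, changed from 0.14 to 1.36, a difference of 1.18 in the joint edgeR fit (SE 0.16, adjusted p = 1.23e-05). Of 137 genes called at both ages 131 had the same sign, with Pearson's correlation at 0.382 and Spearman's at 0.292 across 8529 genes.

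With source oil, 707 of 8272 genes differed between 24 and 72 hpf (z test with normal p), 385 higher and 322 lower at 72 hpf, and the assignment of counts to symbols differs between these tables. BCL6B changed from -0.06 to 1.93, a difference of 2.0 (SE 0.17, z test, adjusted p = 1.07e-29), and its relative BCL6 differed by 1.79. The normal p ignores the few libraries behind the SE and is too small. The urocanate hydratase UROC1 differed by -2.10 and the gluconeogenic G6PC and PCK1 by -1.85 and -1.23. Photoreceptor genes were lower at 72 hpf in 8 of 21 cases, or 10 adjusted over the list alone, and cholesterol-synthesis genes higher in 9 of 20 and lower in 1. Of 307 genes called at both ages 291 had the same sign, with Pearson's correlation at 0.447 and Spearman's at 0.345 across 8272 genes.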

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

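Chosen only after the result was seen were the medians of the photoreceptor and lens lists with slick oil at 48 hpf, the comparison of eye genes with other rising genes for slick oil, the fit with the 48 hpf library as an added slick-oil control, and the splits with the block. The test of a sequencing-run difference was added late, with its bounds written before its value was seen. The results of the next 3 paragraphs are here because a direct test found that 2 effects of oil differed, between the oils or between ages. After them come other splits of the libraries and 3 patterns that were weighed. Differences are given as the second log2 fold change minus the first (slick minus source, or later minus earlier age), and those at 24 hpf between oils compare tables with different assignments of counts to symbols.

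Between the oils at 24 hpf, 63 genes differed. Higher with slick oil were the mannose receptor MRC1 by 1.95, the protease CAPN3 by 1.02 and the lens genes CRYBB1 by 1.36, CRYBA1 by 1.32 and CRYBA2 by 1.18. Lower were the lipase LIPG (-1.89), complement C3 (-1.04), the pyrimidine-degrading DPYD (-0.83), A2ML1 (-1.01) and UROC1 (-0.99), the last of which lost its call once source-oil fold changes were scaled to slick oil (-0.29).

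Between the oils at 72 hpf, 1470 genes differed. Higher with slick oil were the photoreceptor genes UNC119 by 1.19, ARR3 by 1.06, CNGA3 by 1.12 and the clock genes PER3 by 1.72 and PER1 by 1.71, while 6 of 18 clock genes were lower and 7 higher, and the clock list did not pass (adjusted p = 0.285). The transcription factors BCL6B (-1.87), BCL6 (-1.45) and NPAS4 (-2.45), with catalase CAT (-1.16), were lower.

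For slick oil the controls change from the slick series at 24 and 48 hpf to the source series at 72 hpf, so these differences contain that between the series, where PKHD1L1 was higher by 1.07 and RRM2 stood at -0.47 without oil at 48 hpf. Between 48 and 72 hpf with slick oil, 674 genes differed. Higher at 72 hpf were NR1D2 (1.80), ZNF395 (1.79), PER3 (1.61), PKHD1L1 (1.2) and the neuronal calcium channel CACNA1A (0.94). Lower were CAT (-1.19), RRM2 (-1.13), the clock-related receptor RORB (-0.98), XPNPEP1 (-1.08) and UROC1 (-1.5). Between 24 and 72 hpf with slick oil, 379 genes differed, with NOTUM (1.18), NR1D2 (1.18), NADK (1.18), PKHD1L1 (1.09) and FREM2 (1.09) higher at 72 hpf and HABP2 (-1.64), RPL32 (-1.0), AHCY (-0.94) and C6orf58 (-1.78) lower. Between 24 and 72 hpf with source oil, 707 genes differed. BCL6B (2.0), BCL6 (1.79), the protease ADAMTS1 (1.90), PRDM1 (1.58) and MRC1 (2.0) were higher at 72 hpf, and the amino-acid and glucose enzymes UROC1 (-2.10), G6PC (-1.85), BHMT (-1.25), GLDC (-1.17) and PCK1 (-1.23) were lower.

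For groups of 3 against 3, the 10 splits of the libraries are too few for a share under 0.05. The real split alone, 1 of 10, reached its own count in each case: 531 genes for source oil at 24 hpf (highest other 0), 1833 for source oil at 72 hpf (0), 244 for slick oil at 48 hpf (40), 1673 for slick oil at 72 hpf (0), 405 for the 48 hpf controls (2) and 1470 between the oils at 72 hpf (0). For source oil at 24 hpf, where the numbers were taken to pair the libraries, 3 other splits part all 3 pairs as the real one does. They gave 0 genes with the block, against 852. The 6 others part 1 pair. For slick oil between 48 and 72 hpf, 4 of 100 splits gave as many genes as the real 674, and the highest other gave 1197. For source oil between 24 and 72 hpf, 11 of 100 splits gave as many as the real 707, and the highest other gave 1950. In both cases the highest other was the split that exchanges oil and control at 1 age only, which turns the difference into a sum of the effects of oil, so these large counts point to a structure of the samples, the response to oil at both ages. Since such splits let the effects of oil themselves into the count, they decide nothing about chance for these 2 differences.

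The count for slick oil at 24 hpf, 196 here, was larger than the 51 of the authors' deposited table. With the 48 hpf library as an added control, as in that table, 17 genes were called, in line with the explanation that an older library among the controls widens their spread. DESeq2 on the same 5 libraries called 106, between the bounds set for and against the count test as the cause, so the part played by the test stays open. No biological explanation was tested, since both counts come from the same oil libraries.

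The difference between the oils at 72 hpf has technical candidates in a difference between the 2 series of larvae and in a separate sequencing run of the slick-oil libraries. Across 1429 of the 1470 genes, the difference between the oils correlated with that between the 48 hpf controls of the series at 0.333 (95% interval 0.274 to 0.39), an interval that includes the bound of 0.3 set for this cause, so series and oil cannot be told apart for these genes; 1028 (71.9%) had the same sign in both. A run that shifts slick-oil libraries alike was weighed through the correlation with slick oil over control, which would also cross the runs. At 48 hpf it was -0.369 across 1426 genes (95% interval -0.422 to -0.314), below the bound of 0.1 set against this cause. At 24 hpf it was 0.0363 (95% interval -0.0311 to 0.104), an interval that includes that bound. Both fold changes hold the response to oil as well as any run effect, so they cannot decide about a run, which stays open. The slick-series controls at 48 hpf also enter the correlations of 0.333 and -0.369 with opposite sign, so these values are not independent of each other. A weaker response to 1 oil along the same genes is argued against as the sole cause. After the source-oil fold changes were scaled, 1404 genes were still called (the slope of slick on source oil was 0.611). A difference between the series would also leave such calls, so a weaker response beside it stays open. The different doses and compositions of the oils stay among the open explanations, as untested.

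Photoreceptor and lens genes fell at 72 hpf with both oils, which share their controls. With slick oil at 48 hpf, where the controls are separate, photoreceptor genes had a median of -0.64 (95% interval -0.72 to -0.44). Photoreceptor genes were thus lower against separate controls as well. The interval resamples genes and leaves out the spread between libraries, so control libraries that stand apart are not excluded as a cause for photoreceptor genes. The photoreceptor list did not pass there with an estimated correlation (camera, adjusted p = 0.322). For lens genes this cause stays open, since their median there was -0.29 with an interval (95%, -0.32 to -0.25) that includes the bound of -0.3. A general delay of development was weighed through genes outside the eye lists whose controls rose at least as much from 24 to 48 hpf. With slick oil their median was 0.03 (95% interval -0.05 to 0.08, 247 genes) against -0.52 for 41 eye genes. That is past the bound set against a delay. With source oil the median of these other genes was -0.30 (95% interval -0.36 to -0.27, 248 genes) against -0.89, between the bounds set. A partial delay cannot be told apart from an effect on the eye there. Genes that rise only between 48 and 72 hpf were not examined, and series and slick oil differ together at 72 hpf. A delay therefore stays open with slick oil as well. An effect of oil on the developing eye stays open as a hypothesis, found and tested on the same data, beside a difference between the series for slick oil at 72 hpf (photoreceptor median -0.25 between the controls without oil).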

How the results depend on the processing

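Added after the data were seen were the fit with the 48 hpf library as a slick-oil control, the fit of 5 tables together, the replicate block in lists and differences, the block on header numbers, the fits without each library for differences, overlaps and lists, and the subsets and scalings named as added above; the other alternatives were fixed before the data were examined. The cause of the changed counts below was not tested, except that stricter thresholds call fewer genes by construction. DESeq2 called 351 genes instead of 531 for source oil at 24 hpf, 1183 instead of 1833 at 72 hpf, 106 instead of 196 for slick oil at 24 hpf and 961 instead of 1673 at 72 hpf. A replicate block, where the numbers were taken to pair the libraries, called 852 for source oil at 24 hpf and 112 instead of 63 between the oils at that age. For source oil at 24 hpf it gained CASQ2, GRIA3, GRIA1, UCP2 and PSMD2 and changed no other call among the named genes, and the 16 lists that passed did so with it. In the other comparisons the libraries share only a number. In slick oil at 24 hpf (correlations of -0.0201 and -0.00901) the block called 198 genes. There it lost HSPA5, BAG3, GINS2 and CLOCK, gained CP and PCNA, and changed no other call among the named genes tested. At 48 and 72 hpf a block on the number in the column header called 2013 genes for source oil at 72 hpf (same-number correlations of -0.0224 to 0.228), 98 instead of 244 for slick oil at 48 hpf (-0.493 to 0.00128), 1627 at 72 hpf (-0.2 to 0.0054) and 51 instead of 405 for the controls (-0.421 to -0.0249). In none of these 4, nor in source oil at 24 hpf, did every library correlate best with its own number. Of the named genes in these 4, 325 results stayed, 52 calls were lost and 1 was gained. With the 48 hpf library as an added control, slick oil at 24 hpf had 17 genes, and the direction turned for CP (0.22), APOB (0.23), C3 (0.26), PGK1 (-0.09), NPAS2 (-0.18) and CLOCK (-0.01), of which CLOCK had been called. In 1 fit of 5 tables slick oil at 48 hpf had 425 genes instead of 244. At an adjusted p under 0.01 the counts were 308 and 1107 for source oil at 24 and 72 hpf, 118, 108 and 984 for slick oil at 24, 48 and 72 hpf, and 84 for the 48 hpf controls (405 at 0.05). At 0.1 they were 438 for slick oil at 48 hpf, 804 for the controls, 109 between the oils at 24 hpf (63) and 1098 between 48 and 72 hpf (674). With an absolute log2 fold change of at least 1 they were 136 and 336 for source oil, 54, 60 and 206 for slick oil, and 49 for the controls. Scaling left 38 genes between the oils at 24 hpf, and genes at or above the median level left 431 of 707 between 24 and 72 hpf with source oil. Among such genes the correlations rose to 0.619 between the oils at 24 hpf, 0.446 and 0.515 for slick oil at 24 hpf with 48 and 72 hpf, and 0.578 for source oil between 24 and 72 hpf. With an estimated correlation 1 list passed for source oil at 24 hpf, 1 at 72 hpf, 1 for slick oil at 24 hpf, 0 at 48 hpf, 1 at 72 hpf and 0 for the controls, where the preset gave 16, 15, 15, 16, 15 and 14. A correlation of 0.05 left 10 for slick oil at 48 hpf.

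Without each library in turn, the counts ran from 344 to 571 for source oil at 24 hpf and from 1307 to 1833 at 72 hpf. For slick oil they ran from 63 to 489 at 24 hpf and 102 to 941 at 48 hpf, with a lowest count of 1129 at 72 hpf, and for the controls from 96 to 1202. They ran from 34 to 179 between the oils at 24 hpf and 966 to 1559 at 72 hpf. For slick oil they ran from 0 to 190 between 24 and 48 hpf, 351 to 1191 between 48 and 72 hpf and 205 to 471 between 24 and 72 hpf, and for source oil from 472 to 730. Where this left 1 control of slick oil at 24 hpf, that library was assumed to vary like the others. The shared falls of slick oil at 24 and 48 hpf ran from 1 to 28 (9 with all libraries). The direction turned, with no call where it did, for TNNT2 with source oil at 24 hpf (-0.10 to 0.15), PCNA with slick oil at 48 hpf (-0.12 to 0.09), and TNNT2 (-0.23 to 0.00) in the controls.

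Of 587 results for named genes 486 were called, and 354 of these kept call and direction in every alternative run. In oil and control comparisons DESeq2 left 464 the same, with 41 calls lost and 11 gained. Leaving out 1 library left 2762 the same, with 335 lost and 68 gained. The 5-table fit lost 24 and gained 18, and the added control lost 30. Of 91 list results 4 passed in every alternative; an estimated correlation lost 87, a correlation of 0.05 lost 21, ranks lost 7 and leaving out 1 library lost 46. In simulated data at this depth and number of libraries, 41.8 to 71.6% of changes of 1.5-fold were called and 79.1 to 91% of 2-fold changes, so absent calls for small changes say little.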

Other observations

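Tests were not run for the values here beyond those of the main comparisons, and the gene groups were chosen after their values were seen. Some heme and mitochondrial genes rose with both oils, while the red-cell and heme list went both ways. It had 3 genes up and 1 down of 15 with source oil at 24 hpf, or 5 called adjusted over the list alone (adjusted p = 0.634). At 72 hpf it had 6 up and 4 down of 12, or 11 called (adjusted p = 0.0324, and 0.414 with an estimated correlation). With slick oil 2 of 12 rose at 24 hpf, or 3 (adjusted p = 0.0395, and 0.364 with an estimated correlation), and the list did not pass at 48 hpf (2 up, 1 down, adjusted p = 0.44) or 72 hpf (3 up, 1 down, adjusted p = 0.0572). FECH, which inserts iron into heme, rose by 1.67 and 1.76 on the log2 scale with source oil at 24 and 72 hpf, and by 1.22, 1.13 and 1.55 with slick oil at 24, 48 and 72 hpf. UROD, another enzyme of that pathway, rose by 0.44 and 0.82 with source oil and by 0.82 and 0.56 with slick oil at 48 and 72 hpf, and did not pass the test with slick oil at 24 hpf (0.38, edgeR adjusted p = 0.0783, and 0.0412 without oil replicate 3). ALAS2, the first and limiting step in red cells, rose with source oil by 0.53 and 1.04 and with slick oil at 24 and 72 hpf by 0.65 and 0.68. The globin HBE1 fell by 2.0 and 1.06 with source oil and by 0.80 and 1.04 with slick oil at 48 and 72 hpf. ALAS2 at 24 hpf with slick oil lost its call without either control or without oil replicate 1 or 2 (0.57, 0.74, 0.73 and 0.41), and DESeq2 called neither it nor HBE1 with source oil at 24 hpf and slick oil at 72 hpf. The iron-sulfur subunit SDHB rose by 1.71 and 1.59 with source oil and by 1.23, 1.07 and 1.26 with slick oil, alongside SDHA (1.39, 1.03, 1.08, 0.77 and 0.86) and NDUFV1 (1.07, 1.1, 0.80, 0.78 and 0.81) in the same order. The respiratory-chain list passed with source oil at 24 hpf, where 8 of 39 genes rose, or 10 adjusted over the list alone (adjusted p = 5.51e-10, and 0.364 with an estimated correlation), and with slick oil at 24 hpf (3.36e-05, and 0.176). It did not pass with source oil at 72 hpf (adjusted p = 0.0997) or with slick oil at 48 hpf (0.291) and 72 hpf (0.225), where 14 of 37 genes fell and 5 rose, or 22 called adjusted over the list alone.

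Some DNA-repair and clock genes changed as well, while their lists mostly did not pass. The damage sensors XPC and DDB2 rose with source oil by 1.22 and 1.46 at 24 hpf and by 1.68 and 1.11 at 72 hpf, and with slick oil by 1.90 and 1.18 at 72 hpf. The stress gene GADD45A rose at 72 hpf by 2.45 with source and 1.25 with slick oil. In the p53 list 6 genes rose and 3 fell of 22 with source oil at 72 hpf, or 9 called adjusted over the list alone (adjusted p = 0.414 with an estimated correlation, in a range of 0.00396 to 0.414 over the alternatives; without control replicate 2 the preset test gave 0.0787, from 0.0216 with all libraries). The p53 list did not pass with source oil at 24 hpf (adjusted p = 0.109) or with slick oil at 24 (0.275), 48 (0.0923) and 72 hpf (0.541, 3 genes up and 3 down). The clock list passed with slick oil at 24 hpf, where 3 of 18 genes rose, or 3 adjusted over the list alone (adjusted p = 0.00845). It did not with an estimated correlation (0.525), with a correlation of 0.05 (0.051), or without oil replicate 1 (0.0592) or 2 (0.0832). The clock output gene TEF rose by 0.84, 0.63, 0.66, 0.47 and 1.13 for source oil at 24 and 72 hpf and slick oil at 24, 48 and 72 hpf. Its call was lost with slick oil at 24 hpf without control replicate 2 (0.63), and at 48 hpf without the third control (0.40) or the second oil library (0.44). With slick oil at 72 hpf, 15 of 18 clock genes were called, 7 higher and 8 lower, or 18 adjusted over the list alone, with rises in NR1D2 (1.22) and PER3 (1.32) and a fall in RORB (-0.99). The list had a median of -0.29 while its test pointed up, and it did not pass (adjusted p = 0.831). The deposited labels give no time of day of sampling, and whether the groups were sampled at the same hour was not tested.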
